A study of Arabidopsis thaliana with 14 samples.

How the data were processed

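Total RNA from Arabidopsis thaliana seedlings was hybridised to 1-colour expression arrays with 22810 probe sets, 14 arrays in all. The values used are linear intensity values, deposited by the authors as 1 table over the whole series, and MAS5 and limma are named in the submitters' processing notes with versions not given in the sources used here. MAS5 summarises the probes of a probe set into 1 background-adjusted signal. The mean after trimming 2% of probe sets at each end was 500 on every array, so the deposited values had already been scaled to a common level. Detection calls, scanner images and probe-level values were not used here. The number of arrays, 2 per group, limits the precision of every value.

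Groups were taken from the sample titles and descriptions. Wild-type (Col) and det2 seedlings formed 7 groups of 2 replicates, numbered in the titles. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The brassinolide (BL) dose and duration and the light intensity were not given in the sources used here, and the labels call the hormone BL in the dark groups and BR in the groups moved to light.

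Each array was scaled again to a trimmed mean of 500, which moved values by at most 8.82e-05 of themselves. The 64 control probe sets were set aside, and 17787 probe sets with a mean of at least 50 over the 14 arrays were kept, which removed 4959. Values were tested as log2(value + 16), so fold changes are on that scale and understate the change of low genes. Among the named genes and the members of the gene lists, 13 results past the test had a group mean under 16, where the constant sets much of the change. Folds of these are written as at least that value, because the constant lowers them, and their place in an order of size is not known. This sets no bound for the spread between arrays. For THI2.2 in light with BL, leaving out 1 array gave 19.6-fold against 26.7-fold. A linear model with 1 mean per group was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3, with a variance trend over mean level, so all groups share an estimate of the spread. Figures were drawn with matplotlib 3.10.9. Adjusted p-values are Benjamini-Hochberg within each of the 8 comparisons, with 0.05 as the threshold and no minimum fold.

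Probe sets were named through the platform annotation supplied for the value table. It lists 14016 probe sets, 13513 with 1 gene and 503 with several genes, and 8794 probe sets are unnamed here. Of those with 1 gene, 13436 matched a current reference entry. Most named probe sets carry only a locus identifier. For the 147 genes with several probe sets, the probe set with the highest mean over all arrays was used. Named genes followed a rule set before the data were examined. In each comparison it takes the 6 largest rises and 6 largest falls that pass, belong to 1 gene and do not overlap between groups on any array, up to 4 passing members of each list described with the largest changes (or at most 2 where none passes), and a short list of brassinosteroid and light genes, of which only EXPA8 and LHCB4.2 have a named probe set. For the interaction the rule takes 4 and 4.

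Before the data were examined, 25 gene lists with 467 genes were fixed. Only 76 of those genes have a named probe set and 74 were tested, so 11 lists reached the minimum of 3 members. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 88 combinations of list and comparison. The list calls made with the preset correlation numbered 36, and 0 held with a correlation estimated per list. A further 22 gene families were defined by symbol or genome compartment after the probe names were read and before any fold change was computed, and tested in the same way over 176 combinations, with 23 calls at the preset correlation and 0 with an estimated one. No probe set of DET2 is named here, so the mutated gene checks no label.

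The replicate numbers were checked for pairing by the correlation, across probe sets, of each array's deviation from its group mean. Between wild-type groups all 6 correlations lay between 0.226 and 0.429. Between det2 groups the 3 correlations lay between -0.033 and 0.016, and between genotypes the 12 lay between -0.048 and 0.042. The numbers were therefore read as pairing the wild-type arrays, though with only 2 numbers per group, and as names alone for det2. Blocked counts stand beside the wild-type results. Except in the fits to wild-type arrays alone, the block was a term shared by both genotypes. Blocked values for det2 comparisons therefore take a pairing that the det2 arrays did not show.

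Agreement between comparisons was measured as the correlation of log2 fold changes across probe sets, which are not independent replicates. Overlaps of calls are set against the count for independent lists. All comparisons use the same estimate of the spread for a probe set, so some probe sets may pass more readily in every comparison. That count is therefore a reference and not a test. For comparisons sharing arrays, 100 draws of unchanged groups, made without replicate pairing, gave the value expected from the shared arrays. The pipeline was tested on simulated data of 17787 probe sets, drawn without replicate pairing. Known changes of 1, 2 and 3 log2 units were added to 67, 67 and 66 of them. For BL in dark-grown wild type, 55.2% of changes of 1 log2 unit, 97% of changes of 2 and 100% of changes of 3 were recovered, with 6 false calls among 174. For the interaction the shares were 19.4%, 82.1% and 93.9%, with 5 false calls among 135. Alternatives fixed before the data were examined were the values as deposited, quantile normalization, pseudocounts of 1 and 64, no filter, a filter at 150, the replicate number as a block, a fit to fewer groups and each array left out in turn. The block within wild-type arrays alone and the fit without the dark-grown det2 arrays were added after seeing the data.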

Results

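Transcript levels were measured on 14 arrays of Arabidopsis seedlings to ask how brassinosteroids, the plant steroid hormones, act in the change from growth in darkness to growth in light. Wild-type Col seedlings 7 days old were grown in the dark, with or without brassinolide (BL, the most active brassinosteroid), and further wild-type seedlings from each of these conditions were moved to light for 2 h. The mutant det2, described by the labels as brassinosteroid deficient, was grown for 7 days in the dark or in the light, and a group 14 days old was grown in light and then kept in the dark for 8 h. Each of the 7 groups had 2 arrays. The median signal per array lay between 187.9 and 218.6, and replicates of a group correlated at r = 0.963 or above across probe sets.

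**Figure D1:**
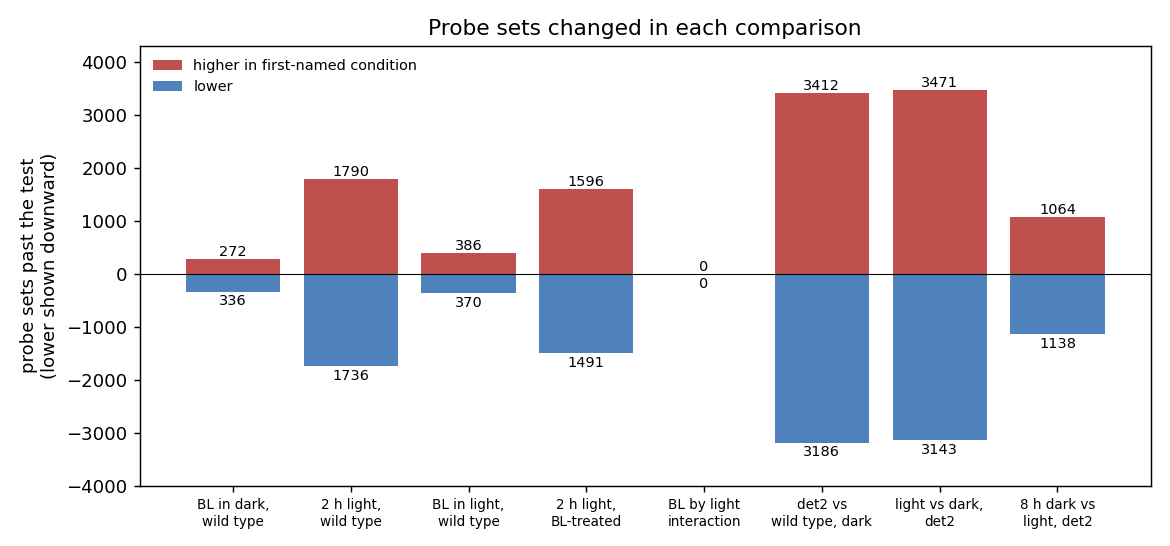
Numbers of probe sets past the test (y axis, higher upward and lower downward) in the 8 comparisons (x axis). Light in wild type gave 1790 higher and 1736 lower, BL in the dark 272 and 336, and the interaction 0.

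BL in dark-grown wild type lowered AT2G16005 most, from 3386 ± 459 to 99.6 ± 13.8 signal units (SD, n = 2), a 29.4-fold fall (adjusted p = 9.58e-08). AT4G37220 fell 16.9-fold and AT5G57785 fell 14-fold, followed by AT4G17470, AT2G39040 and AT5G35940 with falls of 8.88-fold, 7.5-fold and 7.47-fold. The largest rises were those of AT5G19890 (6.91-fold), AT1G53690 (6.79-fold), AT3G60650 (6.44-fold), AT4G14090 (5.44-fold), AT1G49570 (5.32-fold) and AT4G36430 (5.13-fold). Of the 5 measured flavonoid and anthocyanin synthesis genes, 2 rose and 3 did not pass (4 rose adjusted over the list alone), and the list shifted upward with a median log2 change of 1.15 (camera, adjusted p = 0.00122). That list's call was lost, adjusted p = 0.228 with an estimated correlation. Its 2 passing members were DFR (AT5G42800), dihydroflavonol reductase of the anthocyanin branch, which rose by 1.51 ± 0.34 on the log2 scale (SE), and the glycosyltransferase gene UGT78D2 (AT5G17050), by 1.15 ± 0.23.

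Genes of cell wall expansion shifted upward with BL in the dark as a list of 13, with a median log2 change of 0.47 (adjusted p = 0.00248), although 0 members passed alone and 4 were higher adjusted over the list alone. The call was lost, adjusted p = 0.221 with an estimated correlation. The largest values were 1.27 ± 0.41 for XTH20 (adjusted p = 0.137) and 1.22 ± 0.55 for XTH33 (adjusted p = 0.321), both genes of xyloglucan-modifying enzymes. The 3 root markers had a median of -1.45 (adjusted p = 0.0132, and adjusted p = 0.203 with an estimated correlation), with 0 passing and 3 lower adjusted over the list alone. EXPA7 and EXPA18, expansin genes of root hairs, stood at -1.50 ± 0.67 and -1.45 ± 0.51. The light-harvesting list (median -0.21, adjusted p = 0.265) and the photosystem list (median -0.17, adjusted p = 0.0873) did not pass. EXPA8 (0.09 ± 0.24), LHCB4.2 (-0.04 ± 0.13) and EXO (0.46 ± 0.34), a brassinosteroid-responsive gene, did not pass.

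In all, 608 of 17787 probe sets passed with BL in the dark, 272 higher and 336 lower, and 375 of them changed at least 2-fold. With the replicate number as a block 791 passed, and log2 changes within replicate 1 and within replicate 2 correlated at r = 0.553 across probe sets. With wild-type arrays alone the count was 175, and 826 when the replicate number was added to that fit as a block, a fit chosen after seeing the data. It fell to 184 without replicate 1 of the BL-treated seedlings and to 287 without replicate 2 of the untreated ones. Without replicate 1 of the BL-treated seedlings AT4G14090, DFR and UGT78D2 no longer passed (adjusted p = 0.082, 0.218 and 0.165), and DFR was also lost without any of the other 3 arrays and UGT78D2 without either untreated array. All 3 were also lost with wild-type arrays alone (adjusted p = 0.0561, 0.114 and 0.0576) but passed there with the replicate number as a block (adjusted p = 0.00635, 0.0212 and 0.0127). The fold of AT5G57785 lay between 8.4 and 23.4 when either untreated array was left out, and that of AT4G17470 between 5.2 and 15.2 when either BL-treated array was.

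With light for 2 h in wild type, AT5G48570 rose 60.3-fold, from 48.05 ± 16.6 to 3980 ± 1770 signal units (SD, n = 2), and Hop3 (AT4G12400), a co-chaperone gene, rose 42.5-fold. AT5G51440 rose 34.7-fold, AT5G12110 rose 23.5-fold, the methionine sulfoxide reductase gene MSRB6 (AT4G04840) rose 16.4-fold and AT3G56290 rose 15-fold. Falls were led by AT5G57760 (11.3-fold), AT2G34020 (6.87-fold), AT4G11610 (6.49-fold), AT3G01260 (6.4-fold), AT2G28270 (5.81-fold) and AT4G25260 (5.5-fold). Of the early light response genes, HYH (AT3G17609), a bZIP factor related to HY5, rose by 2.56 ± 0.27 on the log2 scale and FHL (AT5G02200), which acts in phytochrome A nuclear import, fell by 1.97 ± 0.28. The clock gene GI (AT1G22770) rose by 2.53 ± 0.52. Only 1 gene of the heat shock list, HSP22, was measured, so that list was not tested. It read 146.5 and 171.2 in the dark and 393.4 and 244.3 in light. With BL it read 223.5 and 218.8 in the dark and 1487.1 and 298.8 in light. No wild-type group was moved without light, so light and other effects of the move, such as heat or handling, cannot be told apart. The same limit holds for light in BL-treated seedlings.

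All 5 flavonoid and anthocyanin genes rose with light in wild type (also 5 adjusted over the list alone), with a median of 2.86 (adjusted p = 1.87e-06, and adjusted p = 0.203 with an estimated correlation). UGT78D2 rose by 3.45 ± 0.23, CHIL (chalcone isomerase-like, AT5G05270) by 2.86 ± 0.30 and UGT79B1 by 2.56 ± 0.38. UGT84A1 read 4.65 in the dark and 212 in light, a rise that depended on the pseudocount, at 3.46 ± 0.38 with 16, 5.23 with 1 and 2.00 with 64. All 4 photosystem and electron transport genes rose (4 adjusted over the list alone, median 1.33, adjusted p = 5.91e-06, and adjusted p = 0.203 with an estimated correlation), led by PSAN (AT5G64040) of photosystem I at 1.84 ± 0.15 and PSBY (AT1G67740) of photosystem II at 1.46 ± 0.12. The 3 measured light-harvesting genes, all encoding the CP29 antenna protein, rose (3 adjusted over the list alone, median 1.36, adjusted p = 0.000378, and adjusted p = 0.203 with an estimated correlation). LHCB4.3 rose by 1.77 ± 0.18, LHCB4.2 by 1.36 ± 0.13 and LHCB4.1 by 0.68 ± 0.16. All 3 Calvin cycle genes rose (3 adjusted over the list alone, adjusted p = 0.0015, and adjusted p = 0.221 with an estimated correlation), with RCA, the rubisco activase gene, at 1.23 ± 0.16, SBPASE at 1.11 ± 0.15 and PRK at 0.75 ± 0.21. LHCB4.1 and PRK no longer passed without replicate 2 of the dark-grown seedlings (adjusted p = 0.0776 and 0.21), nor without replicate 1 of the seedlings moved to light, and PRK not without replicate 2 of those either. With wild-type arrays alone their adjusted p was 0.0515 and 0.102, and with the replicate block in those arrays 0.00438 and 0.0163.

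Auxin genes went down with light, 4 of 6 falling (5 adjusted over the list alone), with a median of -1.17 (adjusted p = 0.000614, and adjusted p = 0.221 with an estimated correlation). GH3.3, an auxin-conjugating enzyme gene, fell by 1.90 ± 0.19, IAA29 by 1.89 ± 0.24, the homeodomain gene HAT2 by 1.48 ± 0.20 and GH3.17 by 0.86 ± 0.17. Of the 13 cell wall genes 3 rose and 5 fell (3 and 7 adjusted over the list alone), and the list did not pass (adjusted p = 0.245). XTH33 fell by 2.26 ± 0.55, XTH19 by 1.77 ± 0.27 and EXPA9 by 1.41 ± 0.27, whereas EXPA16 rose by 1.45 ± 0.28. EXPA8 also fell (-1.10 ± 0.24). XTH33 was lost without replicate 2 of the dark-grown seedlings (adjusted p = 0.0688) or replicate 1 of those moved to light (adjusted p = 0.0887), and of the 8 passing cell wall genes 5 were kept without replicate 2 of either group. Of the 5 starvation genes 2 fell, MCCA by 1.76 ± 0.44 and IVD by 0.78 ± 0.18 (2 adjusted over the list alone), and the list, with a median of -0.66, did not pass (adjusted p = 0.0794) except with the replicate number as a block (adjusted p = 0.0461). Both were lost without replicate 1 of the dark-grown seedlings (adjusted p = 0.125 and 0.0709), and MCCA also without replicate 2 of those moved to light. With wild-type arrays alone MCCA and IVD were lost (adjusted p = 0.0598 and 0.0519), but passed with the replicate block in those arrays (adjusted p = 0.000209 and 0.0113). In chlorophyll synthesis 3 genes rose and PORB, a protochlorophyllide reductase gene, fell (-1.30 ± 0.14). The list did not pass (5 rose and 1 fell adjusted over the list alone, adjusted p = 0.105).

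Light in wild type changed 3526 probe sets, 1790 higher and 1736 lower, 1770 of them at least 2-fold. With the replicate number as a block 4015 passed, and the changes within each replicate correlated at r = 0.752. With wild-type arrays alone 2253 passed, and 3924 with the replicate block in those arrays.

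**Figure D2:**
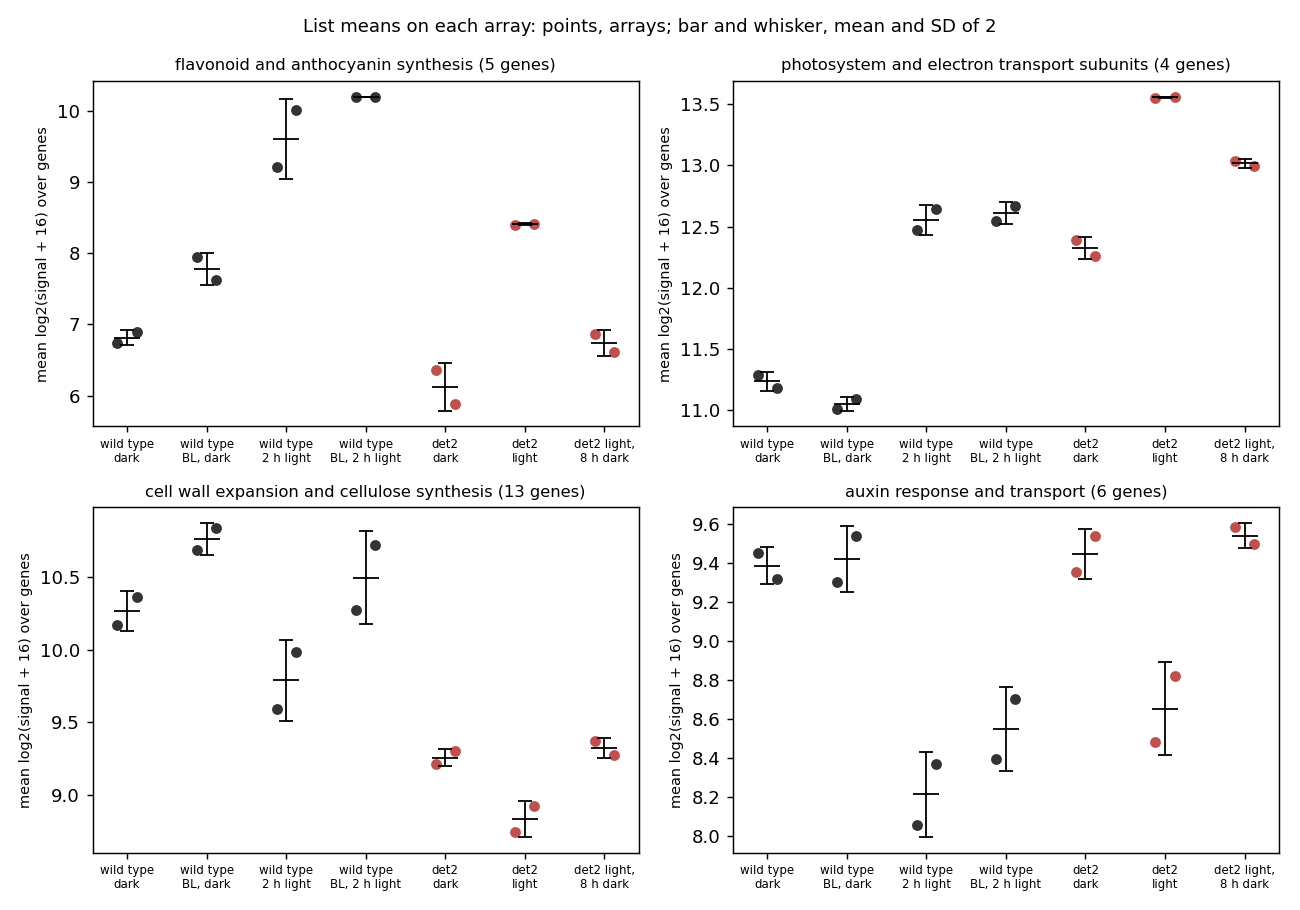
Mean log2(signal + 16) over the genes of 4 lists (y axes) in the 7 groups (x axes), with each of the 2 arrays as a point and the mean and SD as bar and whiskers. The photosystem list stood at 11.24 in dark-grown wild type and at 12.55 after 2 h of light, and the cell wall list at 10.27 in dark-grown wild type and 9.26 in dark-grown det2.

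BL in wild type moved to light shifted genes of cell wall expansion upward, 5 of 13 rising and EXPA16 falling (7 and 1 adjusted over the list alone), with a median of 0.75 (adjusted p = 0.000564, and adjusted p = 0.203 with an estimated correlation). XTH19 rose by 2.09 ± 0.27, XTH18 by 1.07 ± 0.23 and EXPA8 by 1.03 ± 0.24, while EXPA16 fell by 1.13 ± 0.28. The other risers were EXPA4 (0.84 ± 0.16) and COB (0.68 ± 0.14). Only XTH19 still passed with each array left out in turn, and of the 6 passing genes 2 were kept without replicate 2 of either group. EXPA4 was lost without replicate 2 of the BL-treated seedlings (adjusted p = 0.0563) and COB without their replicate 1 (adjusted p = 0.0881) or without replicate 2 of the others. The rest ended at adjusted p = 0.0984 for XTH18 without replicate 1 of the BL-treated seedlings, and at 0.222 for EXPA8 and 0.289 for EXPA16 without their replicate 2. XTH18 was lost without any of the 4 arrays, EXPA8 also without either array of the seedlings without BL and EXPA16 without replicate 2 of those.

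The dark and sugar starvation list shifted down with BL in light, 2 of 5 falling (2 adjusted over the list alone, median -0.87, adjusted p = 0.000564, and adjusted p = 0.203 with an estimated correlation). Its passing members were AKINBETA1, a subunit gene of the SnRK1 kinase, which fell by 1.28 ± 0.32, and IVD, an enzyme gene of leucine breakdown, which fell by 0.87 ± 0.18. Both were lost without replicate 1 of the seedlings moved to light without BL (adjusted p = 0.287 and 0.0999) and without either of the BL-treated arrays, and AKINBETA1 also under quantile normalization (adjusted p = 0.0589). With wild-type arrays alone both were lost (adjusted p = 0.17 and 0.113), as were the cell wall genes COB, EXPA4, EXPA8 and EXPA16 (adjusted p = 0.121, 0.0873, 0.141 and 0.116), and all 6 passed with the replicate block in those arrays (at most adjusted p = 0.0447, for EXPA16). The 3 root markers had a median of -1.11 (adjusted p = 0.0303, and adjusted p = 0.221 with an estimated correlation), with 0 passing, also adjusted over the list alone. EXPA7 stood at -1.84 ± 0.67 and EXPA18 at -1.11 ± 0.51. The largest single rises were those of AT5G50335 (13.7-fold), AT1G53690 (9.27-fold), the beta-glucosidase gene BGLU28 (7.99-fold), AT1G53080 (at least 7.53-fold), AT4G36430 (5.37-fold) and AT2G41090 (5.28-fold). The largest falls were those of AT4G37220 (22.5-fold), AT2G16005 (15.8-fold), AT5G57785 (10.1-fold), AT1G52070 (8.93-fold), AT5G67430 (7.07-fold) and AT3G49960 (at least 6.64-fold). AT5G67430 was lost without replicate 2 of the BL-treated seedlings (adjusted p = 0.0678) and without replicate 1 of the others (adjusted p = 0.0582). Leaving out 1 array moved the fold over 1.5 times for 4 of the 12 genes with the largest changes, AT4G37220 (13 to 39), AT5G67430 (3.66 to 13.6), AT1G52070 (5.32 to 15) and BGLU28 (4.69 to 13.6).

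BL in light changed 756 probe sets, 386 higher and 370 lower, and 1012 with the replicate number as a block. The changes within each replicate correlated at r = 0.513. With wild-type arrays alone 214 passed, and 1006 with the replicate block in those arrays. The count was 299 without replicate 2 of the BL-treated seedlings and 350 without replicate 1 of the seedlings without BL.

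In a comparison chosen after seeing the data, across the 17787 probe sets the effects of BL in the dark and in light, which share no array, correlated at r = 0.629 (Spearman 0.478, covariance 0.131). Of the 339 probe sets that passed in both, 148 were higher in both and 190 lower in both, against 5.9 and 6.99 for independent lists, and 1 went opposite ways.

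**Figure D3:**
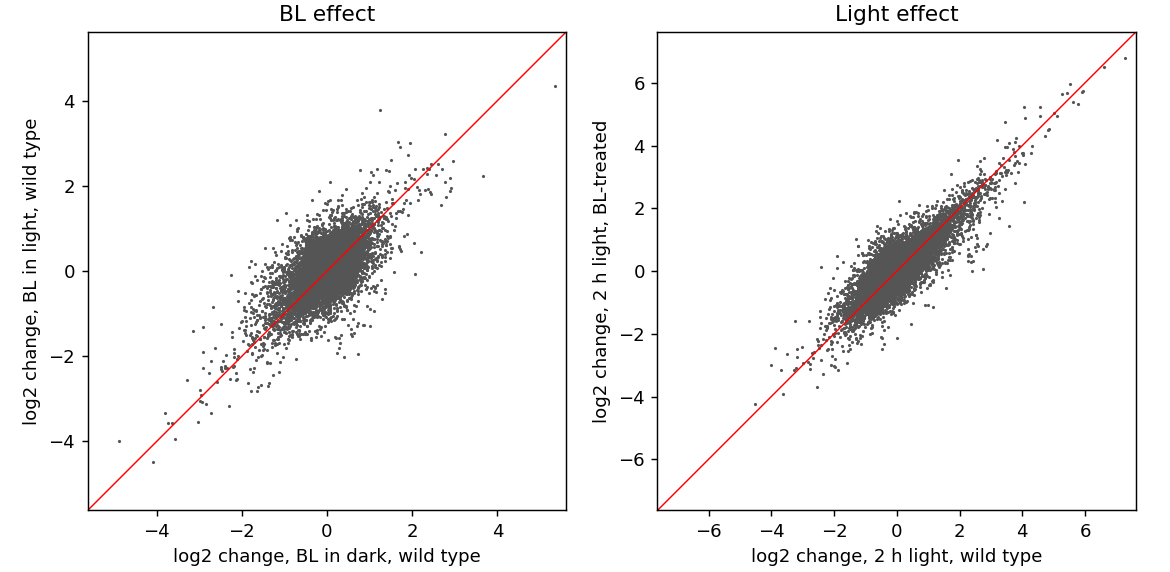
Log2 change of every tested probe set with BL in the dark (x axis) against BL in light (y axis), left, and with light without BL (x axis) against light with BL (y axis), right. Each point is 1 probe set and the line marks equal change. The correlations are 0.629 and 0.839.

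Light in BL-treated wild type raised the same lists as light alone. All 5 flavonoid genes rose (5 adjusted over the list alone, median 2.49, adjusted p = 5.91e-06, and adjusted p = 0.203 with an estimated correlation), with UGT78D2 at 2.62 ± 0.23 and CHIL at 2.49 ± 0.30. All 4 photosystem genes rose (4 adjusted over the list alone, median 1.58, adjusted p = 1.87e-06, and adjusted p = 0.203 with an estimated correlation), led by PSAN at 2.03 ± 0.15. All 3 light-harvesting genes rose (3 adjusted over the list alone, median 1.54, adjusted p = 5.16e-05, and adjusted p = 0.203 with an estimated correlation), with LHCB4.3 at 2.42 ± 0.18 and LHCB4.2 at 1.54 ± 0.13. Of the Calvin cycle genes 2 of 3 rose, RCA and SBPASE (3 adjusted over the list alone, adjusted p = 0.00248, and adjusted p = 0.221 with an estimated correlation). HYH rose by 3.35 ± 0.27 and FHL fell by 1.97 ± 0.28.

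Of the 6 auxin genes 4 fell with light in BL-treated seedlings (5 adjusted over the list alone, median -1.05, adjusted p = 0.0013, and adjusted p = 0.243 with an estimated correlation), with GH3.3 falling by 1.45 ± 0.19 and IAA29 by 1.33 ± 0.24. Of the 5 starvation genes 3 fell (4 adjusted over the list alone, median -1.22, adjusted p = 0.00287, and adjusted p = 0.221 with an estimated correlation), with MCCA, of leucine breakdown, falling by 2.39 ± 0.44 and IVD by 1.25 ± 0.18. AT5G48570 rose 52.2-fold, Hop3 50.7-fold, AT5G51440 31-fold, AT5G12110 30.9-fold, the thionin gene THI2.2 (AT5G36910) at least 26.7-fold and AT1G53540 18.8-fold. Falls were led by AT3G13760 (8.98-fold), AT2G34020 (8.62-fold), AT1G72290 (8.32-fold), COR27 (8.01-fold), AT5G02580 (7.06-fold) and AT1G77200 (6.97-fold). AT1G77200 was lost without 3 of the 4 arrays, at most at adjusted p = 0.125 without replicate 2 of the BL-treated seedlings moved to light. AT1G53540 read 1289 ± 1330 in light (SD, n = 2), and its fold was 7.62 without replicate 1 of those seedlings and 46.6 without replicate 2. Leaving out either of these arrays also moved the folds of Hop3 (33.8 to 76), AT3G13760 (4.76 to 16.9), AT1G72290 (4.51 to 15.3) and AT1G77200 (4.53 to 10.7).

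Light in BL-treated seedlings changed 3087 probe sets, 1596 higher and 1491 lower, and 3553 with the replicate number as a block. The changes within each replicate correlated at r = 0.751. With wild-type arrays alone 1979 passed, and 3516 with the replicate block in those arrays. The count was 1989 without replicate 2 of the dark BL-treated seedlings and 2004 without replicate 1 of those moved to light. The effects of light with and without BL, which share no array and were also compared after seeing the data, correlated at r = 0.839 (Spearman 0.728, covariance 0.403), and of 2289 probe sets passing in both, 1306 were higher and 983 lower in both and 0 went opposite ways.

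The difference between the light effects with and without BL passed for 0 probe sets with limma, where 662 had an unadjusted p under 0.05 against 889 expected by chance, and with the replicate number as a block for 0. A part shared by wild-type replicates cancels in this difference but stays in the unblocked spread, so that fit may find too few. With the block in wild-type arrays alone, chosen after seeing the data, 2 passed. The 0 calls do not show that the light effects are equal. In simulated data with 67, 67 and 66 probe sets changed by 1, 2 and 3 log2 units, 19.4%, 82.1% and 93.9% were found. So many true changes ease the adjusted threshold, and a few real differences would be found less often. The simulated noise also held no replicate pairing, so these shares do not give the power of this test. As lists, light-harvesting genes had a median difference of 0.29 (adjusted p = 0.0293, and adjusted p = 0.262 with an estimated correlation) and photosystem genes of 0.24 (adjusted p = 0.0423, and adjusted p = 0.297 with an estimated correlation). The starvation list had a median of -0.47 (adjusted p = 0.0176, and adjusted p = 0.262 with an estimated correlation). In all 3 lists 0 members passed, also adjusted over the list alone. With the replicate number as a block the photosystem list did not pass (adjusted p = 0.0549), and with wild-type arrays alone neither it (adjusted p = 0.118) nor the light-harvesting list (adjusted p = 0.0616) did.

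Dark-grown det2 differed from dark-grown wild type in 6598 probe sets, 3412 higher and 3186 lower, 3117 of them at least 2-fold. Genes of photosynthesis were higher in det2. All 4 photosystem genes passed (4 adjusted over the list alone, adjusted p = 0.000987, and adjusted p = 0.203 with an estimated correlation), with PSAE1 (AT4G28750) higher by 1.46 ± 0.13, PSAN by 1.11 ± 0.15, PSBW by 0.90 ± 0.15 and PSBY by 0.87 ± 0.12. All 3 light-harvesting genes passed (3 adjusted over the list alone, median 1.07, adjusted p = 0.00546, and adjusted p = 0.221 with an estimated correlation), with LHCB4.2 higher by 1.27 ± 0.13, LHCB4.3 by 1.07 ± 0.18 and LHCB4.1 by 1.04 ± 0.16. The 3 Calvin cycle genes were higher as well (3 adjusted over the list alone), but the list did not pass (adjusted p = 0.0525, and 0.0481 with the replicate number as a block), and PRK and SBPASE were lost without replicate 2 of the wild type (adjusted p = 0.272 and 0.155) or without either det2 array.

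Cell wall genes were lower in dark-grown det2, 6 of 13 passing as lower and 0 as higher (6 and 0 adjusted over the list alone), with a median of -0.82 (adjusted p = 0.000614, and adjusted p = 0.203 with an estimated correlation). XTH18 was lower by 2.75 ± 0.23 on the log2 scale (log2 change -2.75), XTH20 (-2.50 ± 0.41), XTH19 (-1.64 ± 0.27) and EXPA9 (-1.53 ± 0.27) followed, and EXPA8 stood at -0.82 ± 0.24 (lost without replicate 2 of det2, adjusted p = 0.116, or replicate 2 of the wild type, adjusted p = 0.0779). Of the auxin genes 2 were higher and 2 lower (2 and 3 adjusted over the list alone, adjusted p = 0.89), with GH3.3 at 2.29 ± 0.19 and GH3.17 at -1.20 ± 0.17. The gibberellin receptor genes GID1B (-1.65 ± 0.23) and GID1A (-0.75 ± 0.18) were lower in det2, though their list of 4 did not pass (2 lower adjusted over the list alone, adjusted p = 0.213). Of the 3 root markers EXPA18 was lower (-1.68 ± 0.51) and PYK10 higher (0.69 ± 0.12), with 2 lower and 1 higher adjusted over the list alone, and the list, with a median of -1.68, did not pass (adjusted p = 0.868). EXPA18 was lost without replicate 2 of det2 (adjusted p = 0.195) or of the wild type (adjusted p = 0.185). The reference gene GAPC2 passed as higher (0.42 ± 0.10) and was lost without replicate 1 of det2 (adjusted p = 0.0596). PYK10 and GAPC2 turned to lower values under quantile normalization, -0.297 and -0.263, neither passing.

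The largest rises in det2 in the dark were in plastid-encoded transcripts. psbC, a photosystem II core gene, stood at 14120 ± 7.23 signal units in det2 and 499.7 ± 161 in wild type (SD, n = 2), 28.1-fold higher. psbA was 26.5-fold, rps15 24.5-fold, rpl20 20.5-fold and psbT 19.2-fold higher, with AT1G50290 at 22.5-fold. The 2 wild-type arrays differed widely for psbA (703.2 ± 704), rpl20 (486.4 ± 419) and psbT (383.3 ± 397). Without replicate 1 or replicate 2 of the wild type the folds were 11.3 and 62 for psbA, 15.9 and 37.6 for rps15, 10.4 and 40.5 for rpl20 and 8.03 and 46.1 for psbT. Of 69 plastid-encoded genes 66 passed as higher (68 adjusted over the list alone, median 2.86, adjusted p = 3.73e-26, and adjusted p = 0.446 with an estimated correlation). Of 12 mitochondria-encoded genes 11 passed as higher (12 adjusted over the list alone, median 1.88, adjusted p = 1.98e-05, and adjusted p = 0.446 with an estimated correlation). The strongest falls were in AT5G23830 (at least 70.1-fold), AT4G07820 (69.6-fold), AT1G52100 (21.7-fold), ZW9 (AT1G58270, 20.4-fold), AT1G60730 (17.2-fold) and AT5G04120 (17.1-fold). Leaving out replicate 1 or replicate 2 of det2 took AT4G07820 to 35.1-fold or 138-fold and AT5G04120 to 7.53-fold or 38.9-fold.

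The dark-grown det2 arrays stood apart from the wild-type arrays on control probe sets. The ratio of 3' to 5' actin signal was 5.11 and 6.35 on the 2 det2 arrays and between 0.942 and 1.53 on the 8 wild-type arrays. For GAPDH this ratio was 1.28 and 1.39 on the det2 arrays and between 0.931 and 1.08 in wild type. RNA quality was not measured beyond these ratios. The highest signal was 45069.5 and 47536.8 on the 2 det2 arrays and between 18322.5 and 21958 on the wild-type arrays. Sizes of change at high signal may therefore depend on the scaling. The calls of the lists fixed in advance held under quantile normalization, at the preset correlation. The 5S rRNA probe set read 1625 or more in dark-grown det2 against at most 475.3 in wild type, and the 25S rRNA probe set read 838.3 or more against at most 109.9. Genotype and array set cannot be told apart in this comparison, and that limit holds for every gene and list named in it.

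**Figure D4:**
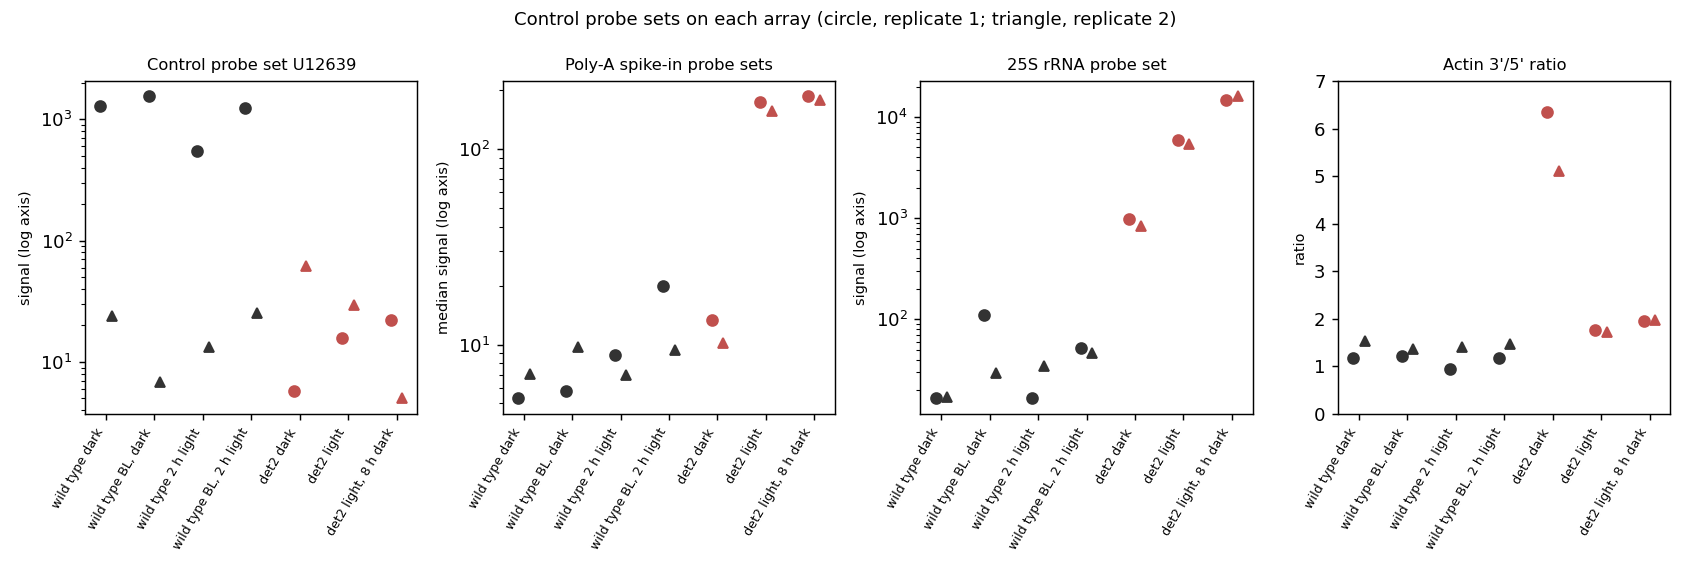
Signals of control probe sets on each array (y axes, log scale in the 3 left panels) by group (x axes), with replicate 1 as circles and replicate 2 as triangles. The 25S rRNA signal is 838.3 or more on every det2 array and at most 109.9 on wild-type arrays. U12639 is 545.6 or more on the 4 wild-type replicate 1 arrays and at most 25.1 on the wild-type replicate 2 arrays.

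Against light in BL-treated wild type, with which it shares no array, the det2 effect in the dark correlated at r = 0.233 (Spearman 0.226, covariance 0.136). Of 1570 probe sets passing in both, 561 were higher and 535 lower in both, against 306 and 267 for independent lists, while 219 were higher in det2 and lower with light and 255 the reverse, against 286 each. Against BL in light, also without shared arrays, r was 0.156 (Spearman 0.143, covariance 0.0622), with 69 higher in both against 74, and 175 lower in both against 66.3. Opposite directions gave 50 higher in det2 and lower with BL against 71, and 116 lower in det2 and higher with BL against 69.1, so 59.5% of the 410 shared calls went the same way. Within replicate 1 this r was 0.224 and within replicate 2 it was 0.0404. Comparisons that use the same dark-grown wild-type arrays gave r = 0.169 with BL in the dark and r = 0.229 with light, where unchanged groups simulated on those arrays gave 0.501 for each. The covariances were 0.0647 and 0.138 against a simulated 0.0405, and the covariance of BL in the dark with light in wild type was 0.0337 (r = 0.106) against the same 0.0405. The draws held no replicate pairing. A part shared by wild-type replicates cancels between wild-type groups, so the value expected for BL in the dark with light may be lower than 0.0405. Overlaps were 51 higher in both against 52.2 and 182 lower in both against 60.2 for det2 and BL in the dark, 626 against 343 and 651 against 311 for det2 and light, and 58 against 27.4 and 89 against 32.8 for BL in the dark and light. In opposite directions (higher then lower, and lower then higher) the counts were 40 against 64.5 and 86 against 48.7, 234 against 333 and 268 against 321, and 69 against 26.5 and 48 against 33.8. The shares of shared calls with the same direction were 64.9%, 71.8% and 55.7%. Taking 1 comparison from replicate 1 and the other from replicate 2 leaves no shared array, and r was then 0.00329 and 0.131 for det2 and BL in the dark, 0.197 and 0.112 for det2 and light, and 0.121 and -0.0707 for BL in the dark and light. Part of the overlaps may come from the shared controls.

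Light-grown det2 differed from dark-grown det2 in 6614 probe sets, 3471 higher and 3143 lower. AT1G23130 was at least 297-fold higher in light, AT3G16670 82.4-fold, AT5G55450 at least 78.8-fold, ECS1 (AT1G31580) 74.4-fold, AT2G25510 42.2-fold and the defensin gene PDF1.2 (AT5G44420) 28.1-fold. Falls included M17 (AT2G41260, at least 458-fold) and LEA18 (AT2G35300, at least 198-fold), the latter a late embryogenesis abundant gene, whose order is not known as they read 4.1 and 1.7 in light. On the log2 scale they were -10.82 and -10.34 at a pseudocount of 1 and -7.09 and -5.75 at 64. Further falls were those of AT5G44440 (124-fold), AT2G47780 (116-fold), AT2G28490 (97-fold) and AT3G02480 (83.3-fold). M17 and LEA18 read 9199 and 3479 in dark-grown det2. Of the 11 genes in the seed storage and embryo list 0 have a named probe set. A difference in germination or stage between these groups was therefore not tested. The flavonoid list rose, 4 of 5 passing (4 adjusted over the list alone, median 2.87, adjusted p = 0.00248, and adjusted p = 0.249 with an estimated correlation), with UGT79B1 at 3.66 ± 0.38 and DFR at 3.31 ± 0.34. All 4 photosystem genes rose (4 adjusted over the list alone, median 1.13, adjusted p = 0.000829, and adjusted p = 0.203 with an estimated correlation), with PSAN at 1.93 ± 0.15, as did the 3 Calvin cycle genes (3 adjusted over the list alone, median 1.11, adjusted p = 0.00774, and adjusted p = 0.249 with an estimated correlation), with SBPASE at 1.68 ± 0.15. Of the light-harvesting genes LHCB4.2 (0.81 ± 0.13) and LHCB4.1 (0.60 ± 0.16) rose and LHCB4.3 (-0.45 ± 0.18) did not pass (2 higher and 1 lower adjusted over the list alone), and the list did not pass (adjusted p = 0.424). LHCB4.1 was lost without replicate 2 of dark-grown det2 (adjusted p = 0.0697) or of light-grown det2 (adjusted p = 0.0617).

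Auxin genes fell in light-grown det2, 3 of 6 passing (3 adjusted over the list alone, median -0.38, adjusted p = 0.0369, and adjusted p = 0.434 with an estimated correlation), with IAA29 falling by 2.56 ± 0.24. Among the 3, GH3.5 was lost without any of the 4 arrays (log2 change -0.503 without replicate 1 of light-grown det2). Of the starvation genes 3 of 5 fell (4 adjusted over the list alone, median -1.14, adjusted p = 0.0298, and adjusted p = 0.3 with an estimated correlation), with MCCA falling by 1.75 ± 0.44. AKINBETA1, which also fell, was lost without replicate 1 of either group (log2 change -1.147 without that of dark-grown det2). In the cell wall list 1 gene rose and 4 fell (1 and 5 adjusted over the list alone, adjusted p = 0.424), with XTH33 (-2.12 ± 0.55) and EXPA8 (-2.06 ± 0.24) among those that fell. XTH33 was lost without replicate 1 of light-grown det2 (adjusted p = 0.118), where 3 of the 5 passing cell wall genes were kept. All 3 root markers passed, EXPA7 (2.46 ± 0.67) and EXPA18 (1.49 ± 0.51) as higher and PYK10 (-0.49 ± 0.12) as lower (2 and 1 adjusted over the list alone), without a shift of the list (adjusted p = 0.768). Without replicate 2 of dark-grown det2 EXPA18 and PYK10 were lost (adjusted p = 0.293 and 0.0684), and without its replicate 1 EXPA7 was (adjusted p = 0.114). Each was also lost without at least 1 array of light-grown det2, and under quantile normalization PYK10 stood at -0.157 and did not pass (adjusted p = 0.333). The reference gene UBC21 fell (-0.68 ± 0.19), and was lost without 3 of the 4 arrays, at most at adjusted p = 0.0753 without replicate 2 of dark-grown det2. Plastid-encoded transcripts were lower in light, 33 of 69 falling and 1 rising (38 and 1 adjusted over the list alone, median -1.10, adjusted p = 2.91e-06, and adjusted p = 0.592 with an estimated correlation). Leaving out an array of light-grown det2 gave 4395 probe sets for replicate 1 and 4394 for replicate 2. The poly-A spike-in probe sets had a median of 176.05 on the 4 det2 arrays from light-grown plants and at most 13.35 on the dark-grown ones. The actin 3' to 5' ratio was at most 1.96 on the light arrays and at least 5.11 on the dark ones, the 25S rRNA median was 10271.75 against 907.5, and the 5S rRNA median was 48.3 against 1730.45, so growth condition and array set cannot be told apart here. Across probe sets this effect correlated with light in wild type at r = 0.215 (Spearman 0.204, covariance 0.148) and with BL in light at r = 0.0976 (Spearman 0.0934, covariance 0.0444), with no shared arrays. Of 1903 probe sets passing in it and in light in wild type, 816 were higher and 633 lower in both, against 349 and 307 for independent lists, and 222 and 232 went opposite ways against 339 and 316. With BL in light 94 were higher in both against 75.3 and 164 lower in both against 65.4, while 58 were higher in light growth and lower with BL against 72.2 and 122 the reverse against 68.2, so 58.9% of the 438 shared calls went the same way.

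The det2 seedlings 14 days old and kept in the dark for 8 h differed from light-grown det2 of 7 days in 2202 probe sets, 1064 higher and 1138 lower. Starvation genes rose, 4 of 5 (5 adjusted over the list alone, median 1.49, adjusted p = 3.52e-05, and adjusted p = 0.203 with an estimated correlation), with MCCA at 2.26 ± 0.44, AKINBETA1 at 1.96 ± 0.32, IVD at 1.49 ± 0.18 and the autophagy gene ATG8E at 0.99 ± 0.15. Auxin genes rose, 4 of 6 (4 rose and 1 fell adjusted over the list alone, median 0.95, adjusted p = 0.00233, and adjusted p = 0.249 with an estimated correlation), with IAA29 at 2.13 ± 0.24 and HAT2 at 1.13 ± 0.20. Cell wall genes rose, 3 of 13 (5 adjusted over the list alone, median 0.33, adjusted p = 0.0267, and adjusted p = 0.311 with an estimated correlation), led by EXPA16 at 1.81 ± 0.28, and EXO rose by 2.17 ± 0.34. Flavonoid genes fell, 4 of 5 (4 adjusted over the list alone, median -1.46, adjusted p = 0.000256, and adjusted p = 0.221 with an estimated correlation), with DFR at -2.98 ± 0.34 and UGT79B1 at -2.84 ± 0.38. The other passing members were CHIL, lost without replicate 2 of the dark-treated seedlings (adjusted p = 0.0843) or replicate 1 of light-grown det2, and UGT78D2, lost without any of the 4 arrays, at most at adjusted p = 0.0737 without replicate 1 of light-grown det2. Of the cell wall genes XTH16 was lost without any of the 4, at most at adjusted p = 0.153 without replicate 2 of light-grown det2.

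Photosynthesis lists also went down in the older det2 seedlings kept in the dark. Light-harvesting genes fell in 2 of 3 cases (3 adjusted over the list alone, median -0.62, adjusted p = 0.00959, and adjusted p = 0.228 with an estimated correlation), photosystem genes in 1 of 4 (3 adjusted over the list alone, adjusted p = 0.00233, and adjusted p = 0.203 with an estimated correlation) and Calvin cycle genes in 1 of 3 (3 adjusted over the list alone, adjusted p = 0.00774, and adjusted p = 0.249 with an estimated correlation). Chlorophyll synthesis genes fell in 3 of 8 (4 adjusted over the list alone, median -0.45, adjusted p = 0.00501, and adjusted p = 0.262 with an estimated correlation). PSBY fell by 0.97 ± 0.12 and SBPASE by 0.93 ± 0.15, both passing with each array left out, whereas LHCB4.2, which fell by 0.62 ± 0.13, was lost without any of the 4 arrays, at most at adjusted p = 0.0618 without replicate 2 of the dark-treated seedlings. The same held for the other passing light-harvesting gene, LHCB4.3 (at most 0.166, without replicate 1 of the dark-treated seedlings), and for the 3 passing chlorophyll genes, HEME1 (at most 0.119, without that array), HEME2 (at most 0.121, without replicate 2 of light-grown det2) and PORB (at most 0.066, without replicate 2 of the dark-treated seedlings). Both counts were therefore 0 with any array left out. ICL (AT3G21720), the isocitrate lyase gene of the glyoxylate cycle, fell at least 30.6-fold, PDF1.2b 28-fold, AT1G70820 18.1-fold, AT4G14090 at least 17.2-fold, AT2G36145 15.3-fold and PDF1.2 13.4-fold. The largest rises were AT1G50040 (14.4-fold), AT4G23870 (6.87-fold), AT5G04120 (at least 6.59-fold), AT5G57655 (4.92-fold), AT4G25580 (4.91-fold) and AT2G15880 (4.86-fold). AT5G04120 was lost without any of the 4 arrays (at most adjusted p = 0.101, without replicate 1 of light-grown det2) and AT4G25580 without 2 of them (at most adjusted p = 0.0754, without replicate 2 of light-grown det2). The fold of AT1G50040 was 7.56 and 27.3, and that of AT4G25580 2.83 and 8.51, without replicate 2 and replicate 1 of light-grown det2.

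Leaving out 1 array gave 795 and 905 probe sets for replicates 1 and 2 of the dark-treated seedlings and 791 and 883 for those of light-grown det2, while a fit to det2 arrays alone gave 4767. Age and darkness differ together in this comparison. The 25S rRNA probe set read 14609.8 and 16081.9 on the arrays of the older seedlings and 5933.7 and 5396.3 on those of light-grown det2. The effect correlated at r = -0.451 with light growth in det2, with which it shares the light-grown arrays, where unchanged groups gave -0.5. The covariance was -0.243 against a simulated -0.0404. Of 1558 probe sets passing in both, 836 were higher in light growth and lower after the dark and 608 the reverse, against 222 and 188 for independent lists, with 66 higher and 48 lower in both against 208 and 201. With 1 comparison from each replicate, which leaves no shared array, r was -0.371 and -0.336. The reference gene list passed in none of the 8 comparisons, with the smallest adjusted p at 0.424 in light with BL.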

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

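The tests on organelle transcripts, on the det2 genotype and on the 8 h of darkness were chosen after those results were seen, and the test on the mean-level trend was chosen before its value was computed.

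Plastid-encoded transcripts were higher in dark-grown det2 than in dark-grown wild type, with a median of 2.86 over 69 genes. A rise of plastid photosynthesis genes alone is argued against by the mitochondria-encoded genes, whose median was 1.88. More labelling of RNA without poly(A) tails on those arrays would raise mitochondria-encoded genes too, and so would a change of all organelle transcripts with the det2 genotype. These cannot be told apart, because genotype and array set change together, and the medians of 1.88 and 2.86 exclude neither. Means were 2.77 ± 0.15 (SE over genes) for 43 photosynthesis genes and 3.12 ± 0.17 for 19 gene-expression genes of the plastid. From dark to light in det2 these sets had medians of -0.78 and -1.53.

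Probe sets higher or lower in dark-grown det2 tended to go the same way in BL-treated wild type given light, with r = 0.237 over the probe sets outside the organelle lists. A distortion that depends on mean level would have taken this toward 0 once the running median by mean level was removed from both effects, and r was then 0.231. The det2 genotype and the array set cannot be told apart as sources of the remaining relation, since they change together, and a bias that follows transcript features other than mean level was not tested.

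Older det2 seedlings kept 8 h in the dark changed in the direction opposite to wild type given light. The effects correlated at r = -0.268 without shared arrays, and of 903 probe sets passing in both, 760 went opposite ways against 218 for independent lists. This is what 8 h of darkness would give. The 7 more days of age cannot be told apart for the 903 shared probe sets or the rest, because no group of that age stayed in light.

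Signals in control probe sets, which no comparison uses, stood above the level of other arrays. The probe set U12639 read 545.6 or more on the 4 wild-type replicate 1 arrays and at most 25.1 on the 4 replicate 2 arrays. Poly-A spike-in probe sets had a median of 176.05 on the 4 det2 arrays from light-grown plants and 7.95 on wild-type arrays. The 25S rRNA probe set had a median of 10271.75 on those det2 arrays and 32.15 on wild-type arrays. The 5S rRNA probe set had a median of 1730.45 on dark-grown det2 arrays and 132.75 on wild-type arrays.

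The light effect with BL minus that without it differed for 4 lists by camera at the preset correlation. The medians were 0.286 for light-harvesting genes, 0.24 for photosystem genes, -0.465 for the starvation list and -0.309 for plastid-encoded genes (adjusted p = 0.00133). No such list passed with an estimated correlation, where the plastid list had adjusted p = 0.734.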

How the results depend on the processing

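The block within wild-type arrays alone and the fit without dark-grown det2 arrays were chosen after seeing the data. Fits to fewer groups gave 175 probe sets for BL in the dark, 2253 for light and 214 for BL in light. They gave 1979 for light with BL and 4882 for det2 in the dark, and all these counts were lower. Those for light growth in det2 (8728) and the 8 h dark (4767) were higher. Log2 changes are the same in these fits, which differ in the estimate of the spread. The main counts rest on a spread shared by both genotypes. Between replicates 1141 probe sets differed in wild type and 0 in det2. How much of the change in counts comes from this was not tested. With 1 array left out, the lone array being assumed to vary like the other groups, counts ranged from 184 to 526 for BL in the dark, 2658 to 3008 for light, 299 to 965 for BL in light, 1989 to 2630 for light with BL, 4658 to 5518 for det2 in the dark, 4394 to 4965 for light growth in det2 and 791 to 905 for the 8 h dark. The interaction gave 2 probe sets at a pseudocount of 64 and 2 with the block in wild-type arrays alone, and 0 under every other setting run. The cause was not tested. With the replicate number as a block the counts were 791, 4015, 1012, 3553 and 0 in wild type, and 7117, 7156 and 2581 for the det2 comparisons, and 38 list shifts passed against 36. For the det2 comparisons these blocked results take a replicate pairing that det2 did not show. The block ended the call of the photosystem list in the interaction, added those of the starvation list for BL in the dark (adjusted p = 0.0481) and for light and of the Calvin list for det2 in the dark, and moved no count of calls by over 1.5 times in the fit to all arrays. Within wild-type arrays alone it gave 826, 3924, 1006 and 3516.

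The 36 list shifts became 0 with an estimated correlation and kept their direction elsewhere. Correlations between comparisons moved by more than the SD of the 2 within-replicate correlations in 6 pairs. That SD is smaller than the difference between the 2, so some of these moves lie inside that difference. For det2 in the dark with light in BL-treated seedlings they were 0.212 under quantile normalization and 0.225 at a pseudocount of 64 and at a filter of 150. For light growth in det2 they were 0.22, 0.228 and 0.236 with light in wild type, 0.11 and 0.118 with BL in light (pseudocount 64 and filter 150), and -0.445, -0.482 and -0.476 with the 8 h dark. At a filter of 150 BL in the dark and BL in light correlated at 0.708 and light with and without BL at 0.891. GAPC2 and PYK10 in dark-grown det2 turned to -0.263 and -0.297 under quantile normalization, and the cause was not tested. Of 267 gene results past the threshold, 196 passed under every setting run, 70 were lost with at least 1 array left out, 27 in the fit to fewer groups, 10 under quantile normalization besides the 2 that turned, 7 with no filter, 5 without the dark-grown det2 arrays, 4 at a pseudocount of 1, 2 with the block in wild-type arrays alone, 1 at a pseudocount of 64 and 0 with the block in all arrays. The values as deposited gave 3086 for light with BL against 3087 and the same counts elsewhere, and since they were already scaled this tests little. Signal over background was not available beyond the filter on low values.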

Other observations

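The gene families below were defined by symbol after the probe names were read and before fold changes were computed, and no hypothesis is attached to them. SWEET genes, which encode sugar transporters, fell with BL in the dark in 4 of 13 cases, and the family shifted down (median -0.17, adjusted p = 0.00958, and adjusted p = 0.446 with an estimated correlation). SWEET3 fell by 2.18, SWEET11 by 1.79, SWEET2 by 1.53 and SWEET16 by 1.45 on the log2 scale. The same 4 fell with BL in light, where SWEET13 rose by 1.33 and the family did not pass (adjusted p = 0.0988). SWEET2 rose by 2.65 with light in wild type and by 3.26 with light after BL.

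Nuclear genes of the NDH complex, which carries electrons around photosystem I in the plastid, rose with light in 5 of 8 cases (median 0.82, adjusted p = 0.00243, and adjusted p = 0.446 with an estimated correlation) and fell in 2 of 8 after the 8 h dark in det2 (median -0.73, adjusted p = 0.00542, and adjusted p = 0.446 with an estimated correlation). NdhN rose by 1.31 with light in wild type and fell by 1.22 after the dark in det2. UDP-glycosyltransferase genes rose in 14 of 38 cases and fell in 6 with light (median 0.52, adjusted p = 0.0121, and adjusted p = 0.446 with an estimated correlation). Of 7 tubulin genes, which encode the subunits of microtubules, 4 fell with light, TUB5 by 1.22, TUB1 by 0.91, TUB6 by 0.74 and TUB9 by 0.57, though the family did not pass (adjusted p = 0.0606). Glutathione transferase genes were higher in 7 of 11 cases in light-grown than in dark-grown det2 (median 0.70, adjusted p = 0.00542, and adjusted p = 0.446 with an estimated correlation) and fell in 4 after the 8 h dark (median -0.27, adjusted p = 0.0353, and adjusted p = 0.446 with an estimated correlation), with GSTU25 at -2.10. In dark-grown det2 against wild type 7 of the 11 were lower and 2 higher (median -0.98), and the family did not pass (adjusted p = 0.0748). The dark-grown det2 arrays stand apart on control probe sets, so the comparison of light-grown with dark-grown det2 cannot separate growth condition and array set.

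Between the replicates of wild type, 1141 probe sets differed with limma, 562 higher in replicate 2 and 579 higher in replicate 1, and 0 differed between the replicates of det2, where 795 had an unadjusted p under 0.05. AT1G54870 was higher by 2.50 ± 0.17 (SE) on the log2 scale in replicate 2 of wild type.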
